A study of Mus musculus with 10 samples.

How the data were processed

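The samples were blood neutrophils of 10 male C57BL/6 mice, hybridized to 10 Affymetrix MG-430 PM arrays after 2-cycle labelling, in which the RNA is amplified more than once. As the labels state it, 5 samples came from individual mice and 5 were portions of 1 pool of blood from the other 5 mice, split before the neutrophils were isolated, so that the pool carries the noise of isolation, RNA extraction, labelling and hybridization but no difference between mice. The authors deposited log2 values, 1 per probe set and array, made with RMA, the 1 tool that their processing notes name. Its version, the background step and whether all arrays were processed together are not stated in the sources used here. The values were checked to lie on a log2 scale without gaps. Their percentiles differed between arrays, so the arrays as deposited do not share 1 common distribution. Arrays give no counts, so their number limits the precision. The 10 columns of values were all used.

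Of 45141 probe sets, 104 controls were set aside, 551 with several gene symbols and 15692 with none were left out of the gene tests, and 28898 carried 1 symbol. Of these, 28689 matched through their gene ID to the gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed by it. Positions are not given because the labels do not name a genome build for the array. The probe set with the highest mean over the 10 arrays stood for each of 17097 genes, and 10734 genes with a mean above 4.58, the median of all probe sets, were tested.

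Each gene's variance between the 5 mice was divided by its variance between the 5 pool arrays, the latter moderated across genes with an intensity trend in limma 3.58.1 (R 4.3.3, data.table version 1.17.8), and tested one-sided in each direction. The Benjamini-Hochberg method was used throughout, with a threshold of 0.05 on the adjusted p. The median variance ratio, the variance ratio of each gene list and the spread of marker levels were tested by exact permutation of the group-centred arrays over all assignments to groups of 5. The smallest p these allow is 0.00397 one-sided and 0.00794 two-sided. The between-mouse SD is the root of the difference of both variances, or 0 where that is negative, and it has no test. Mean levels were compared in limma with the error taken from the individual mice alone, since the pool is 1 sample of 5 mice whose replicates are technical. Gene lists were compared with camera, at a preset correlation of 0.01 and at an estimated one, and with fry. Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 drew the plots.

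The groups, the tests, the gene lists and the rule for named genes were set before the data were examined. The rule takes the 14 genes past the threshold with the largest SD between mice minus SD between pool arrays, the 4 with the largest ratio in the opposite direction (none passed), the 3 members of each list with the largest SD between mice, the 8 largest increases and the 8 largest decreases in mean past the threshold or, where none pass, the 8 genes with the smallest p, and every housekeeping reference. Lists with fewer than 5 tested genes were not tested. These were eosinophil genes with 2, basophil and mast cell genes with 1, and the sex-linked control list with 2. The other 25 lists are 9 of cell type markers and 16 of pathways, stress responses and reference genes.

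The variance test was tested on simulated data of 10734 genes, of which 200 were given a larger variance between mice. With technical variances drawn from the fitted prior it recovered 7.46% of changed genes at a variance ratio of 4, 64.2% at 16 and 92.4% at 64, and 8 unchanged genes made up 6.84% of its calls. With technical variances set to the moderated estimates of the real genes, it recovered 16.4%, 77.6% and 98.5%, and 23 unchanged genes made up 15.2% of the calls. The mean test recovered 25.4% of genes changed by 1 log2 unit, 89.6% at 2 and 100% at 3, and called 2 unchanged genes. In that simulation the between-mouse SD of a gene was at most the median of the real genes, and no array stood apart. Recovery in the real arrays, where many genes vary more, was not tested and can be lower. For a simulated list of 20 genes with a variance ratio of 16, the permutation p was 0.00794, and 8% of unchanged lists had p under 0.05.

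Alternatives were no filter or a filter at the 75th percentile, another quantile normalization, centring each array on its median, the probe set with the median mean, probe sets that can match several transcripts left out, each array left out in turn, other forms of the variance test, a regression on the markers of other blood cells, and other fits of the mean comparison. Alternatives without mice 4 and 5 together, and an ordinary 2-group fit without mouse 5, were added after seeing the data.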

Results

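Messenger RNA was profiled in blood neutrophils, the first white cells to reach a site of infection, from 10 male C57BL/6 mice aged 3 months, after 9 days of acclimatization. The neutrophils of 5 mice were profiled separately, 1 array per mouse, and these biological replicates are called mouse 1 to mouse 5. The blood of the other 5 mice was mixed and split into 5 portions before the neutrophils were isolated, and these technical replicates of 1 sample are called pool 1 to pool 5. Isolation used magnetic beads against Ly6G, a surface protein of mouse neutrophils, and the labels give a purity between 71.5% and 99.5% without a value per sample. The deposited values are log2 array signals, and 10734 genes were tested in the 10 arrays. The number of arrays, 5 in each group, limits the precision of every value.

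The neutrophil genes S100a8 and S100a9, singled out after their values were seen, read 12.28 to 13.29 on the 10 arrays, near the top of the signal range, while mouse 5 gave a weaker signal in most other abundant genes. The median signal of an array lay between 4.50 and 4.74, and its 95th percentile was 7.46 in mouse 5 against 8.72 to 9.25 in the others. The Gapdh control probes at the 3′ end of the transcript read 7.78 in mouse 5 and 11.62 to 12.25 elsewhere. Control transcripts that pass through the amplification with the sample (poly-A spikes) read 5.69 in mouse 5 and 7.31 to 10.44 elsewhere, whereas control RNA added just before hybridization read 11.71 against 9.00 to 10.66. The Actb control probes read higher at the 3′ than at the 5′ end of the transcript by 4.57 in mouse 5, 4.41 in mouse 3 and 1.28 to 2.72 elsewhere, and for Gapdh this difference was 6.16 in mouse 3, the highest of the arrays. The Pearson correlation across all probe sets, which are not independent replicates, was 0.738 to 0.800 between mouse 5 and the other arrays. Mouse 4 correlated at 0.900 to 0.939 with the arrays other than mouse 5, and the remaining 8 arrays correlated at 0.949 or more with each other. The 5 pool arrays correlated at 0.983 to 0.992 and the pair mouse 1 and mouse 2 at 0.994. Mice 4 and 5 carry the sample numbers 9 and 10, the last of the series, and the labels do not say what the order of the numbers means. These arrays shared 0.490% identical values with each other, against at most 0.062% in any other pair and at most 0.0022% between either of them and the other 8 arrays. If this marks a batch, it holds individual mice only. Because of these arrays, the leading values are also given without mouse 5 and without mice 4 and 5, a choice made after the data were seen.

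The study set out to measure how much gene expression in neutrophils differs from mouse to mouse, beyond the noise of the procedure. The genes that differed most between the mice were dominated by mouse 5. Lcn2, a granule protein that withholds iron from bacteria (Entrez gene 16819), read 10.97 to 12.43 in mice 1 to 4 and 5.36 in mouse 5, with an SD of 2.87 among the 5 mice and 0.36 among the 5 pool arrays. Lbr, the lamin B receptor that shapes the lobed nucleus, read 10.34 to 10.72 in mice 1 to 4 and 4.55 in mouse 5, and the splicing kinase gene Clk1 read 10.54 to 10.89 and 4.23. In the pool Lbr read 9.96 to 10.76 and Clk1 9.01 to 10.42.

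The 14 genes with the largest excess of the SD between mice over the SD between technical replicates were Lcn2, Rab5if, Trim25, Lbr, H2az1, Clk1, Hspa5, Ddx5, Scd1, Crebbp, Rps3a1, Hnrnph2, Blk and Naca. Mouse 5 was the lowest array for 13 of them. After mouse 5 was left out, 4 of the 14 still varied more between mice at an adjusted p under 0.05. These were Scd1, a fatty acid desaturase (SD 2.48, n = 4, limma adjusted p = 0.000647), Blk, a B cell kinase (SD 2.27, adjusted p = 0.00022), Naca, a chaperone of newly made proteins (SD 1.66, adjusted p = 0.00179), and Rps3a1, a protein of the small ribosomal subunit (SD 0.97, adjusted p = 0.0304). Scd1 read 9.09 to 10.77 in mice 1 to 3, 5.01 in mouse 4 and 4.54 in mouse 5. For the other 10, the adjusted p without mouse 5 ranged from 0.159 for Lcn2 to 0.978 for Clk1.

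In the moderated variance test (limma, n = 5 against 5), 7165 of 10734 genes (66.8%) varied more between mice than between technical replicates, and 0 varied less, with 1 gene at an unadjusted p under 0.05 in that direction. Without mouse 5 the count was 2176 (20.3%), and without mice 4 and 5 it was 76 (0.708%), all of them among the 7165. In both of these sets, 0 genes varied less between mice, with 52 and 446 genes at an unadjusted p under 0.05. Mouse 5 was farthest from the median of the mice for 5390 of the 7165 genes (75.2%) and mouse 4 for 1289, against 361 for mouse 3, 92 for mouse 1 and 33 for mouse 2. A test on absolute deviations (Levene type, limma), adjusted from a 2-sided p, called 0 genes in either direction. At an unadjusted one-sided p under 0.05, 5754 genes were more variable between mice and 60 less variable.

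The median gene had an SD of 0.57 log2 units between mice and 0.23 between technical replicates, which leaves a between-mouse SD of 0.52. Without mouse 5 the between-mouse SD of the median gene was 0.22, and without mice 4 and 5 it was 0, with an SD of 0.19 between the remaining 3 mice. The 5 mice spanned more than 2-fold for 67.6% of genes and the 5 pool arrays for 12.1%. This share among the mice was 33.3% without mouse 5 and 8.48% without mice 4 and 5, groups of 4 and 3 arrays set against the 5 of the pool. The median SD between mice was 0.38 in the lowest quartile of signal and 1.06 in the highest, against 0.16 and 0.32 in the pool. Without mouse 5 it was 0.25 and 0.38. The share of genes that varied more between mice was 61.0% in the lowest quartile and 76.2% in the highest with all mice, and 24.3% and 10.6% without mouse 5. The median variance ratio was 7.34 (2.88 on the log2 scale), with p = 0.00397 in a one-sided exact permutation test over all assignments of the arrays, the smallest p it can give. It was 2.34 without mouse 5 (exact p = 0.111) and 0.746 without mice 4 and 5 (exact p = 0.625).

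**Figure D1:**
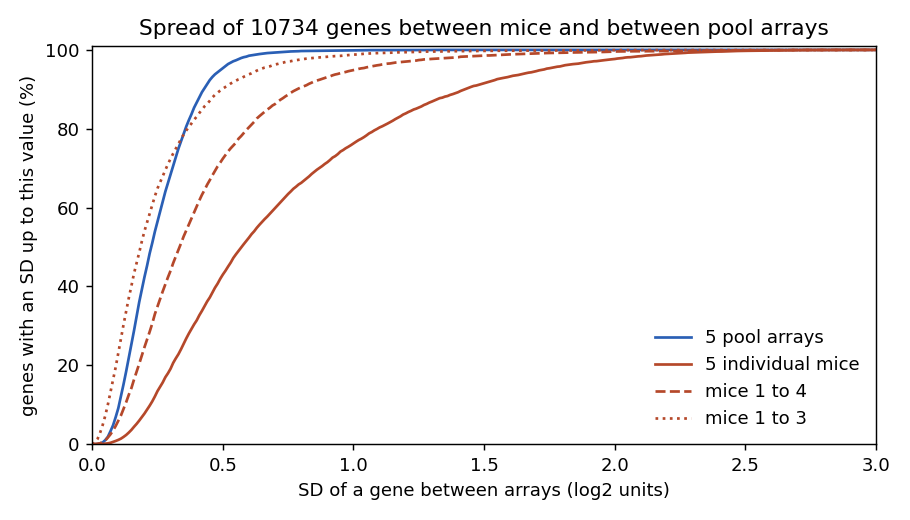
Share of the 10734 tested genes (%, vertical axis) with an SD up to the value on the horizontal axis (log2 units), as 1 curve each for the 5 individual mice, mice 1 to 4, mice 1 to 3 and the 5 technical replicates of the pool. The median SD is 0.57 for the 5 mice, 0.33 without mouse 5, 0.19 without mice 4 and 5 and 0.23 for the pool.

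Some genes of the granules that neutrophils fill late in their development were high in 1 mouse. Camp, the antimicrobial peptide cathelicidin (Entrez gene 12796), read 11.80 in mouse 3, 6.12 to 7.29 in the other 4 mice and 9.50 to 10.65 in the pool, so that the mice spanned 51.5-fold. Ltf, the iron-binding lactoferrin (Entrez gene 17002), read 12.56 in mouse 3, 5.97 to 7.41 in the others and 9.53 to 11.14 in the pool. Chil3, a chitinase-like protein, read 12.22, 6.15 to 7.48 and 8.68 to 9.86, and Ngp, the neutrophilic granule protein, read 13.26, 7.81 to 9.26 and 11.13 to 11.90. Lcn2, of the same immature granule list, was not highest in mouse 3 (11.87) but in mouse 4 (12.43). The level of the whole list, relative to the mean of each gene over the arrays, was -0.56, -0.78, 1.43, -0.13 and -1.69 in mice 1 to 5. The chitinase-like gene Chil4 was likewise highest in mouse 3, at 10.48, 4.51 to 5.57 in the other mice and 6.79 to 7.87 in the pool.

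Of the 15 tested genes of the immature granule list, 11 varied more between mice (11 adjusted over the list alone), 7 without mouse 5 and 6 without mice 4 and 5. Camp, Ltf, Chil3 and Ngp passed in each of these sets, with limma adjusted p of 0.000763, 0.00106, 0.000498 and 0.000498 for mice 1 to 3 against the pool, where the call rests on mouse 3. Without mouse 3 the variance ratio of Ltf was -0.02 on the log2 scale. Genes of the primary granules, made earlier in development, and the precursor gene Ms4a3 stayed low on every array. Elane, Prtn3 and Ms4a3 read 4.72 to 5.95, and Mpo, the gene for myeloperoxidase, read 6.00 in mouse 3 and 4.13 to 4.90 elsewhere. Mouse 3 was the highest mouse in each of these genes, by little in Elane (5.71 against 5.69 in mouse 4) and Ms4a3 (5.24 against 5.20 in mouse 5). Mpo and the immediate early gene Egr1 also varied more between mice without mouse 5 (adjusted p = 0.00066 and 0.000241). Egr1 read 12.88 in mouse 3, 7.40 to 9.80 in the other mice and 11.72 to 12.60 in the pool. Ngp, Chil4, Egr1, Ms4a3 and the primary granule genes were singled out after their values were seen.

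**Figure D2:**
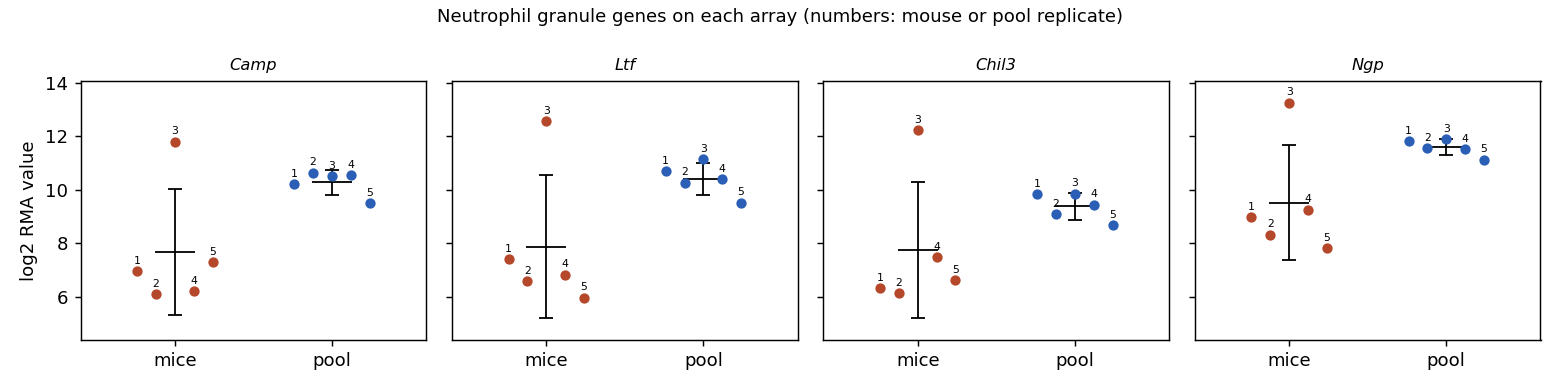
Log2 signal of Camp, Ltf, Chil3 and Ngp on each array, individual mice beside the pool, with points numbered by replicate and black bars for the mean and SD of each group of 5. Mouse 3 reads 11.80 to 13.26, above every pool array, and the other mice read 5.97 to 9.26, below every pool array of the same gene.

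Genes of mature neutrophil functions varied mainly through the low values of mouse 5. Cyba, a subunit of the oxidase that makes superoxide, read 10.65 to 11.39 in mice 1 to 4 and 6.43 in mouse 5, an SD of 2.07 that became 0.30 without mouse 5. Itgb2, the beta 2 integrin chain by which neutrophils hold on to vessel walls, read 12.08 to 12.22 in mice 1 to 4 and 7.80 in mouse 5, with an SD of 1.95 and, without mouse 5, of 0.07. Tlr2, a receptor for bacterial lipoproteins, read 9.08 to 10.26 in mice 1 to 4 and 5.35 in mouse 5.

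In the oxidase and phagocytosis list 18 of 20 genes varied more between mice (19 adjusted over the list alone), with Cyba, Itgam and Rac2 the most variable, and 1 did without mouse 5, the oxidase gene Cybb. In the trafficking and aging list, led by Itgam, Ccr1 and Itgb2, the counts were 15 of 17 (15 adjusted over the list alone) and, by the same limma test, 0 without mouse 5, with 1 gene at an unadjusted p under 0.05. Itgam then had an adjusted p of 0.357. Among pattern recognition receptors, led by Tlr2, Cd14 and Clec4n, 20 of 26 passed (20 adjusted over the list alone) and 1 without mouse 5, the adaptor gene Ticam1. Of the neutrophil markers, led by Lcn2, Ltf and Camp, 18 of 22 passed (18 adjusted over the list alone), 5 without mouse 5 (Camp, Il1r2, Ltf, Ngp and Wfdc21) and 3 without mice 4 and 5 (Camp, Ltf and Ngp). For interferon response genes, led by Oasl2, Gbp3 and Cmpk2, the counts were 21 of 27 (21 adjusted over the list alone) and 2 without mouse 5 (Ddx58 and Gbp3). Gbp3, an interferon-induced GTPase, kept an SD of 1.24 without mouse 5, with 8.93 in mouse 3 and 6.08 to 6.81 in mice 1, 2 and 4. Inflammatory genes, led by Cd69, Ptgs2 and Tnfaip2, gave 20 of 27 (20 adjusted over the list alone) and 5 without mouse 5 (Cd69, Cd83, Il1f9, Ptgs2 and Traf1). Hypoxia and glycolysis genes, led by Pfkfb4, Gapdh and Pkm, gave 20 of 23 (20 adjusted over the list alone) and 1 without mouse 5 (Pfkfb3), and apoptosis regulators, led by Pmaip1, Bid and Apaf1, gave 12 of 20 (12 adjusted over the list alone) and 4 (Bad, Bak1, Bcl2 and Casp9). The members named for the smaller sets were chosen after their values were seen, here and for the lists that follow.

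Genes that follow stress or the time of day were also read. Among immediate early genes, led by Klf2, Junb and Klf6, 20 of 23 varied more between mice (20 adjusted over the list alone), 5 without mouse 5 (Dusp2, Egr1, Egr2, Fosb and Myc) and 3 without mice 4 and 5 (Egr1, Egr2 and Myc). Glucocorticoid response genes gave 14 of 18 (14 adjusted over the list alone) and 4 without mouse 5 (Il1r2, Mt1, Nfil3 and Per1). Their most variable members were Sgk1, a kinase induced by steroids, Nfil3 and Cebpd, with SDs of 2.48, 2.09 and 2.02. The circadian clock list gave 7 of 14 (7 adjusted over the list alone) and 2 without mouse 5, Nfil3 and Per1. These genes, which belong to both lists, read 9.06 (Nfil3) and 10.01 (Per1) in mouse 4 against 6.64 to 7.92 and 7.73 to 8.76 in mice 1 to 3. Both passed without mouse 5, with limma adjusted p of 0.0268 and 0.0265, and neither did without mice 4 and 5. The clock gene Csnk1e had an SD of 1.73, and 0.22 without mouse 5.

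Genes of ribosomal proteins read lower in mouse 4 and mouse 5 than in the other mice, with a list level of -1.20 and -2.37 against 0.35 to 0.99. Rps4x, of the small ribosomal subunit, read 11.97 to 12.91 in mice 1 to 3, 9.30 in mouse 4 and 7.47 in mouse 5. Rps19 read 9.68 to 10.72, 6.13 and 5.53, and Rplp2 read 11.53 to 11.88, 9.54 and 6.27. Of 46 ribosomal protein genes, 44 varied more between mice (44 adjusted over the list alone), 26 without mouse 5 and, by the same limma test, 0 without mice 4 and 5, with 1 gene at an unadjusted p under 0.05. Oxidative phosphorylation genes, led by Atp5c1, Atp5b and Ndufv1, gave 29 of 43 (30 adjusted over the list alone), 8 without mouse 5 and 0 without mice 4 and 5 (3 at an unadjusted p under 0.05). Heat shock and unfolded protein genes gave 19 of 23 (19 adjusted over the list alone), 8 and 1 (Pdia4). In this list the chaperones Hspa5, Calr and Hsp90aa1 had SDs of 2.58, 2.17 and 2.11, and Hsp90aa1 kept an SD of 1.40 without mouse 5. Cell cycle genes gave 12 of 15 (12 adjusted over the list alone), 6 and 1, and the 1 was Stmn1, a protein that destabilizes microtubules, with 8.66 in mouse 3 against 5.48 to 6.99 in the other mice. The replication helicase genes Mcm6 and Mcm2 had SDs of 1.51 and 0.86. Reported targets of the microRNA miR-223 gave 17 of 24 (17 adjusted over the list alone), 5 (Il6st, Mef2c, Parp1, Stmn1 and Tgfbr3) and 2 (Il6st and Stmn1). Il6st, the shared receptor chain of the interleukin 6 family, read 8.49 in mouse 3 and 4.20 to 5.31 in the other mice, while Mef2c had an SD of 1.66 with and without mouse 5 and Sp3 had 2.21 and 0.42.

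Housekeeping references varied between the mice as well. Of the 15 tested, 14 varied more between mice (14 adjusted over the list alone), 2 without mouse 5 (Tfrc and Tubb5) and, by the same limma test, 0 without mice 4 and 5, with 1 gene at an unadjusted p under 0.05. The SD between mice ran from 0.46 for Pgk1 to 2.03 for Eef1a1, followed by 1.96 for Rpl13a and 1.95 for Gapdh. Relative to its mean over the 10 arrays, the list stood at -2.24 in mouse 5. For Hprt alone of the 15, the direction turned after the arrays were quantile normalized again, with a log2 variance ratio of -0.22. Of 25 fixed lists, 0 passed the exact permutation test of the variance ratio against all genes (2-sided). The smallest exact p it can give, 0.00794, comes to an adjusted 0.198 for 1 list, so a single list could not pass, and the 1 with an unadjusted p under 0.05 was that of the apoptosis regulators (shift -0.78, p = 0.00794). Leaving out pool 5 gave 5 lists, those of neutrophil markers, MHC class II, T cells, heat shock and ribosomal proteins, and camera on absolute deviations gave 1 with the preset correlation, that of ribosomal proteins, and 0 with an estimated one.

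Markers of B cells and antigen-presenting cells, which are not neutrophils, differed widely between the mice. Ms4a1, the B cell surface protein CD20 (Entrez gene 12482), read 9.99 to 11.65 in mice 1 to 3, 5.71 in mouse 4, 6.82 in mouse 5 and 8.71 to 10.22 in the pool. H2-Eb1, a chain of the MHC class II molecule that presents antigen, read 11.29 to 11.64 in mice 1 to 3, 7.03 in mouse 4 and 8.45 in mouse 5. The mean level of the 13 B cell genes, relative to the mean of each gene over the arrays, was 0.81, 0.87, 1.69, -2.47 and -1.69 in mice 1 to 5, and 0.82, -0.17, 0.24, 0.01 and -0.09 in pool 1 to 5. That of the 11 dendritic cell and MHC class II genes was 0.70, 0.62, 0.88, -1.80 and -1.54 in the mice, and 0.56, 0.14, 0.34, 0.23 and -0.13 in the pool. Both levels were lowest in mouse 4, then mouse 5, and highest in mouse 3, so the lists are not separate results. In mouse 4 the neutrophil markers stood at 0.20 and the ribosomal protein genes at -1.20, beside the B cell level of -2.47. In mouse 5 the neutrophil markers stood at -2.14 and the housekeeping references at -2.24, lower than its B cell and MHC class II levels. The low levels of mouse 5 therefore do not stand apart from its weaker signal in other lists. Mice 4 and 5 are also the pair with 0.490% identical values, a possible batch.

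The SD of the B cell level was 1.81 between mice and 0.40 between pool arrays, a ratio of 4.54, and that of the MHC class II level was 1.32 and 0.26, a ratio of 5.16. For both lists, p = 0.00794 in a 2-sided exact permutation test, the smallest it can give, and the adjusted p over 9 marker lists was 0.0357. Each list reached this adjusted value only because both stood at the smallest p, and a single list there would not have passed. Without mouse 5 the ratios were 4.62 and 4.96, about as large, while both adjusted p in this test were 0.179. Neither list passed when any 1 mouse, or mice 4 and 5 together, were left out. Without mice 4 and 5 the smallest p the test can give is 0.0179, so a single list could not pass over the 9. Among the others, the level of the platelet list had an exact p of 0.0476 (adjusted p = 0.125), and the neutrophil, immature granule, monocyte, T cell, NK cell and erythroid lists had adjusted p between 0.125 and 0.310. Gene by gene, 11 of 13 B cell genes varied more between mice (12 adjusted over the list alone), 11 without mouse 5 and, by the same limma test, 0 without mice 4 and 5, with 5 genes at an unadjusted p under 0.05. For MHC class II the counts were 9 of 11 genes (9 adjusted over the list alone), 8 and 0, with 0 at an unadjusted p under 0.05. The most variable were Bank1, Pou2af1 and Ms4a1 among B cell genes, with SDs of 2.61, 2.61 and 2.47, and H2-Ab1, H2-Eb1 and H2-DMa among MHC class II genes, with 2.56, 2.10 and 2.02.

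**Figure D3:**
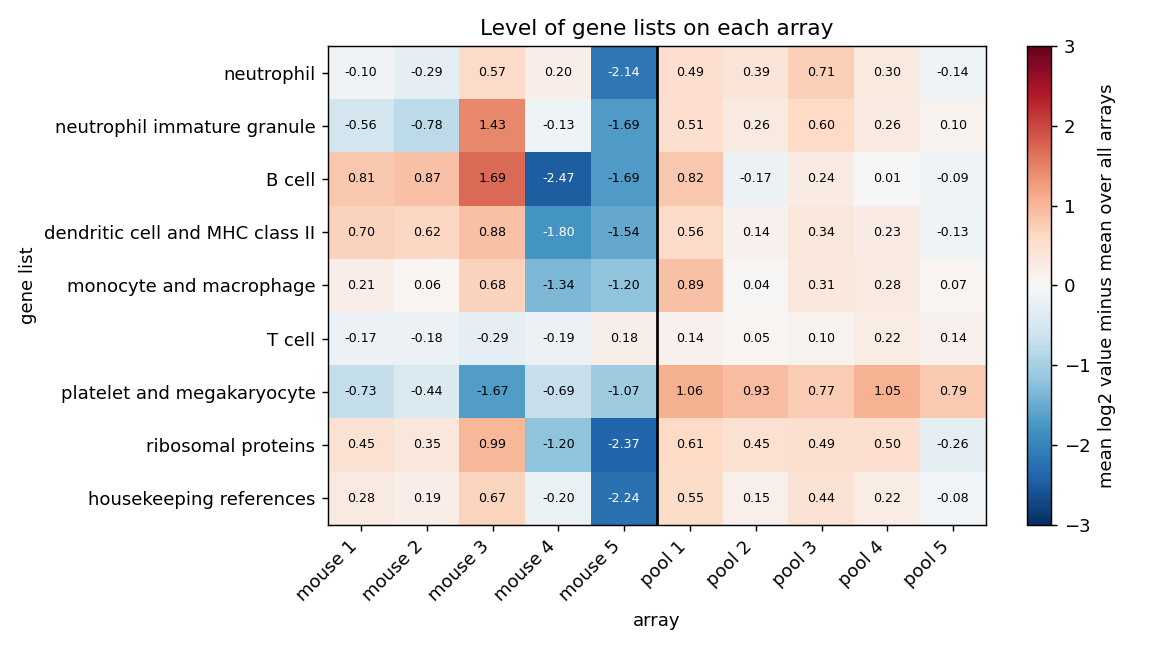
Heat map of the mean level of gene lists (vertical axis) on each array (horizontal axis), in log2 units relative to the mean of each gene over the 10 arrays, printed in each cell and coloured from blue (low) to red (high). The B cell level is -2.47 in mouse 4 and -1.69 in mouse 5 and at least -0.17 on all other arrays.

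Monocyte genes varied more between mice in 14 of 16 cases (16 adjusted over the list alone), 9 without mouse 5 and, by the same limma test, 0 without mice 4 and 5, with 5 at an unadjusted p under 0.05. Klf4, a transcription factor of monocytes, read 9.85 in mouse 3, 7.22 and 7.41 in mice 1 and 2, 4.09 in mouse 4 and 3.38 in mouse 5, and the matrix protein gene Fn1 and the lysosomal gene Cd68 had SDs of 2.50 and 2.06. Erythroid genes gave 12 of 16 (12 adjusted over the list alone), 7 and 0 (1 at an unadjusted p under 0.05). The haemoglobin gene Hbb-b2 read 11.83 to 12.86 in mice 1 to 3, 9.34 in mouse 4 and 7.39 in mouse 5, but also 10.17 to 12.54 within the pool, and Bpgm and Isg20 had SDs of 2.10 and 1.76. T cell genes gave 2 of 9 (Cd8b1 and Cd3d; 1 adjusted over the list alone) and 0 in both smaller sets (2 and 1 at an unadjusted p under 0.05), and Lat had an SD of 0.50 and an adjusted p of 0.0674. NK cell genes, led by Prf1, Klrk1 and Ccl5 with SDs of 0.92, 0.71 and 0.45, gave 7 of 10 (7 adjusted over the list alone), 2 (Ccl5 and Prf1) and 0, with 0 at an unadjusted p under 0.05. Platelet genes gave 10 of 15 (10 adjusted over the list alone), 7 and 1, and the 1 was Gp1bb, with 8.70 in mouse 3 and 10.30 to 12.15 in the other mice.

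Adjusted over the list alone, more members passed in the smaller sets for several lists. Without mouse 5 and without mice 4 and 5, the counts were 9 and 7 for platelets, 9 and 7 for heat shock, and 8 and 9 for the immature granule list. They were 10 and 4 for monocytes (the 4 were C1qa, C1qc, Fn1 and Klf4), 5 and 4 for immediate early genes (the 4 were Egr1, Egr2, Fosb and Myc) and 1 and 1 for the oxidase list (Cybb in both). For B cells they were 12 and 0, for erythroid genes 10 and 0, for cell cycle genes 7 and 1, for ribosomal proteins 35 and 0 and for NK cells 4 and 0 (the 4 were Ccl5, Il2rb, Klrk1 and Prf1). Fewer passed for interferon response (1 and 0, Gbp3), pattern recognition receptors (0 and 0) and housekeeping references (1 and 0, Tfrc), and for the other lists both adjustments gave the same counts.

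Comparing the average of the individual mice with the pool asks whether the blood of 5 other mice, mixed, gave the same mean level. Mixing averages the signal before its log2 is taken, whereas the mice were averaged after it. This lowers the mouse mean of a gene that varies between mice, so part of a higher level in the pool can be built in. The genes nearest to a difference were all higher in the pool. Clca3a2 read 4.22 ± 0.42 in the mice and 6.40 ± 0.49 in the pool (SD, n = 5 each). Pcyt1b, an enzyme of phosphatidylcholine synthesis, read 4.91 ± 0.30 and 6.90 ± 0.35, and the calcium-binding protein gene S100a1 read 4.38 ± 0.19 and 5.87 ± 0.49. Sftpc, Smyd4, Apcdd1, Lancl3 and Cap2 were also higher in the pool. The mouse means of Clca3a2, S100a1, Sftpc, Apcdd1 and Cap2 lay below the filter level of 4.58, so no fold is given for these genes. All 8 were short of the threshold, with an adjusted p of 0.171 in limma.

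In limma with the spread between mice as the error, 0 of 10734 genes differed at an adjusted p under 0.05. At an unadjusted p under 0.05, 38 genes were higher in mice and 522 higher in the pool, the direction that averaging after the log2 favours. The ordinary 2-group limma fit, which treats the technical replicates as if they were mice, called 3 and 285. Without mouse 5 the counts were 2 higher in mice (Ppil4 and Mpp6) and 153 higher in the pool, and without mice 4 and 5 they were 116 and 352. Without mouse 3 it was 1 gene, Mup3, a major urinary protein gene that read 8.54 in mouse 3, 3.23 to 3.87 in the other mice and 6.94 to 9.80 in the pool. Without mouse 5, the 8 largest decreases in mice against the pool were those of Gsta2, Hacd1, Cavin2, Prokr1, Mmp19, Gchfr, Tpm1 and Rab27b. Of these, Prokr1 and Mmp19 had means under the filter level of 4.58 in the mice. In mouse 5 itself, Hacd1, an enzyme of fatty acid elongation, read 9.98, above the pool arrays (7.99 to 9.06), and Cavin2, a coat protein of caveolae, read 11.29, below them (11.43 to 12.10). The median difference over all genes, mice minus pool, was -0.10, and -0.00139 after the arrays were quantile normalized again.

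Platelet genes as a group were higher in the pool. Pf4, platelet factor 4 (Entrez gene 56744), read 11.91 ± 0.30 in the mice and 13.23 ± 0.14 in the pool (SD, n = 5 each), near the top of the signal range, so no fold is given. Gp9, a subunit of the platelet receptor for von Willebrand factor, was 6.56-fold higher and Treml1, a receptor of platelet granules, 5.38-fold. Gp1bb, of the same receptor as Gp9, and Vwf, von Willebrand factor itself, were also higher, with pool means of 12.66 and 12.74 near the top of the range. All 15 tested genes of the list had a higher mean in the pool, by 1.84 log2 units on average.

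By camera with a preset correlation of 0.01, the platelet list was the only 1 of 25 to differ (adjusted p = 2.35e-21), and its adjusted p was 0.0359 with an estimated correlation and 0.000228 by fry. More lists passed by camera, all of them higher in the pool, after single arrays were left out: 5 without mouse 3, 4 without pool 5, 3 without mouse 1 or without mouse 4 and 2 without mouse 2. Gene by gene in limma, 0 of the 15 passed over all genes and 14 adjusted over the list alone. The mean difference, mice minus pool, was -1.80 without mouse 5 and -1.87 without mice 4 and 5, but the adjusted p with an estimated correlation was 0.225 and 0.548. As the pool is 1 sample of 5 mice, fry and camera take its technical replicates as mice. Genes of other lists that platelets or their precursors also express stood higher in the pool too, though chosen after their values were seen and short of the threshold: F13a1 of the monocyte list (5.52-fold, adjusted p = 0.216), Lat of the T cell list (3.86-fold, adjusted p = 0.225) and Gata1 of the erythroid list (3.16-fold, adjusted p = 0.535). For the other 24 lists, the adjusted p by camera lay between 0.0793 and 0.933.

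**Figure D4:**
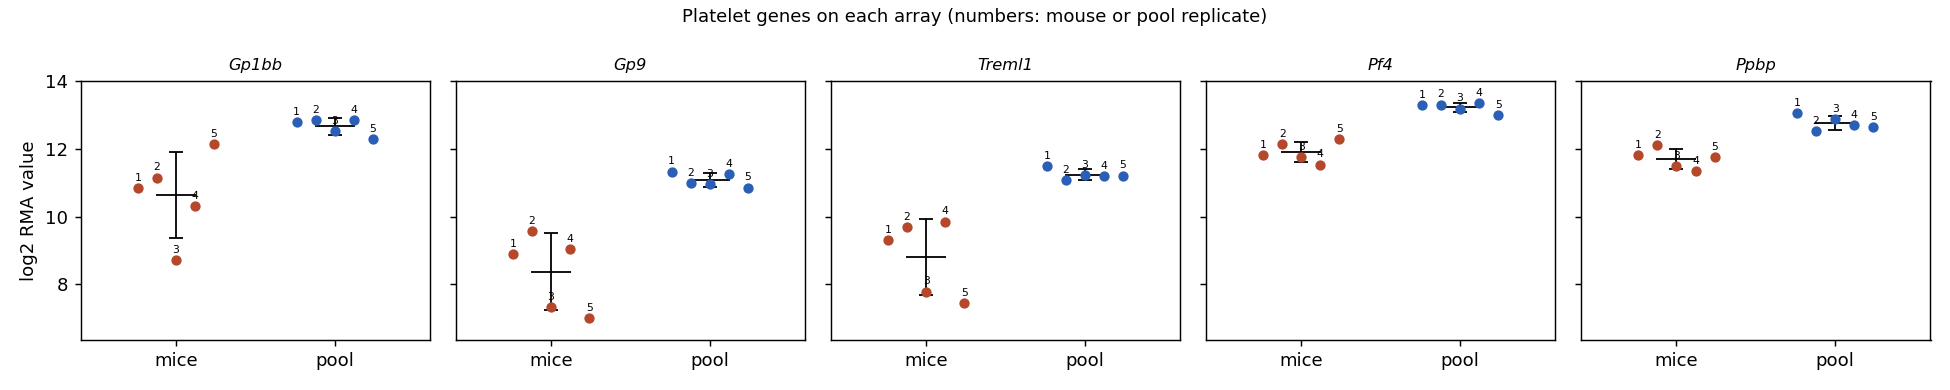
Log2 signal of Gp1bb, Gp9, Treml1, Pf4 and Ppbp on each array, individual mice beside the pool, with points numbered by replicate and black bars for the mean and SD of each group of 5. Pf4 reads 11.54 to 12.28 in the mice and 13.01 to 13.35 in the pool.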

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

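The tests of explanations in this part were all chosen after the results were seen. An array stood apart when its gap to the nearest other array of its group, divided by the range of the 5 arrays, exceeded the 95% critical value of Dixon's test, 0.71 for 5 values. Chance does this in about 1 in 20 groups, and 69 of the 282 groups tested did, over array measures, marker levels, gene lists and 109 named genes. Many of these genes were named for a large SD between mice, which an array apart produces, so an excess over 1 in 20 is partly built in. Mouse 5 was the array apart in most of them. It was the lowest mouse for 41 named genes and the highest for 2.

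Mouse 5 had the lowest values of the mice in 2 array measures, the 95th percentile of the signal (gap over range 0.792) and the 3′ Gapdh control (0.941), and in 8 gene lists. These were the lists of interferon response (0.821), inflammatory genes (0.782), glucocorticoid response (0.803), hypoxia and glycolysis (0.848), oxidase and phagocytosis (0.914), trafficking and aging (0.933), pattern recognition receptors (0.913) and apoptosis regulators (0.858). Its T cell level was the highest of the mice (0.756). In the pool, pool 5 was the lowest array for ribosomal proteins (0.815) and oxidative phosphorylation (0.731).

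For single genes, the gap over range of mouse 5 as the lowest mouse was Lcn2 0.794, Rab5if 0.909, Trim25 0.897, Lbr 0.938, H2az1 0.815, Clk1 0.948, Hspa5 0.776, Ddx5 0.900, Crebbp 0.856, Hnrnph2 0.932, Isg20 0.788, Oasl2 0.951, Cmpk2 0.845, Klf2 0.847, Junb 0.778, Klf6 0.793, Tnfaip2 0.942, Sgk1 0.911, Cebpd 0.802 and Csnk1e 0.871. In a further 21 genes it was Calr 0.754, Pfkfb4 0.759, Gapdh 0.942, Pkm 0.848, Atp5c1 0.732, Atp5b 0.880, Cyba 0.850, Itgam 0.795, Rac2 0.945, Ccr1 0.906, Itgb2 0.968, Tlr2 0.761, Cd14 0.740, Clec4n 0.743, Sp3 0.834, Pmaip1 0.772, Bid 0.855, Apaf1 0.753, Rpl13a 0.725, Ppil4 0.875 and Mpp6 0.925. Mouse 5 was the highest mouse for Cd3d 0.793 and Hacd1 0.772.

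Mouse 3 was the highest mouse, with the gap over range given after each gene, for Ltf 0.783, Camp 0.793, Chil3 0.781, Il6st 0.741, Chil4 0.822 and Ngp 0.734, and the lowest for Gchfr 0.714. Mouse 4 was the lowest for Sftpc 0.761 and Smyd4 0.800. Within the pool, pool 1 was the highest array for Il6st 0.768 and Cnn3 0.772 and pool 5 the lowest for Rplp2 0.725 and Ndufv1 0.759. Since chance sets apart about 1 in 20 groups and the genes were named for a large spread, single calls of this kind say little.

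Probe sets without a single gene symbol took no part in the gene tests. Of 6675 such probe sets with a mean signal over 4.58, 3903 (58.5%) varied more between mice than between technical replicates in the same limma test, 1365 without mouse 5 and 36 without mice 4 and 5.

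The first pattern weighed is the array of mouse 5, far below the other 9 in most abundant genes. Other nucleated blood cells in its sample are argued against as the only cause, since housekeeping genes, which such cells also express, fell too. Their level was -2.47 relative to the mean of mice 1 to 4, whose SD was 0.36. A weak signal lowers housekeeping genes in any cells, so a changed mix of cells besides it stays open. Weak amplification or labelling may account for it. The poly-A spikes, which pass through that step, were -1.62 relative to the lowest of the other arrays. On those arrays the spikes themselves spanned 7.31 to 10.44. The hybridization spikes were not low. The share of genes below the median of mice 1 to 4 was 83.9% in the highest quartile of signal and 32.1% in the lowest, a difference of 51.8 percentage points. Any narrower range of signal would give such shares, so they do not single out that step. Shorter RNA stays open: the difference between 3′ and 5′ ends was the highest of the arrays for Actb (4.57) but the lowest for Gapdh (3.05). The Gapdh probes at the 5′ end read 4.73 in mouse 5, near the median of that array, 4.74. Low signal therefore limits the Gapdh difference, which says little about the length of the RNA. A larger share of platelet RNA in the sample cannot be told apart. The platelet list lay at -0.19 relative to the mean of mice 1 to 4 (SD 0.54). Of its 15 genes, 0 of them in another list, 5 were above the highest of these mice and 5 below the lowest. Pf4 read 12.28 and Ppbp 11.75 in mouse 5, after the selection for Ly6G. For Pf4 this was the highest value of the mice, so the weaker signal did not reach every abundant gene. Mice 4 and 5 processed apart from the other 8 arrays, of which their 0.490% of identical values (at most 0.062% in other pairs) is a sign, and a difference between animals, with 1 array of mouse 5, stay open too, since such a batch would hold individual mice only.

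The second pattern is the high level of Camp, Ltf, Chil3 and Ngp in mouse 3, of which Ngp was singled out after its values were seen. Other blood cells of the 7 marker lists are argued against by the mean level of each list, not by each member. Mice 1 and 2 were not low in B cell level as mice 4 and 5 were. Over mice 1 and 2, the list that rose most in mouse 3 was that of B cells (13 genes, 0 of them in another list, with Ms4a1 at 11.65). It rose by 0.85 (SD 0.40 in the pool), and the whole immature granule list, which holds the 4 genes, by 2.10. Such means can hide single members: the monocyte list rose by 0.55, but its gene Klf4 rose by more. Mice 1 and 2 exceeded mouse 4 by 3.31 in B cell level but stood at -0.34 relative to it in the mean of the 4 genes. A fault of the mouse 3 sample or array stays open: its Actb control was 1.69 above the highest array other than mouse 5 in the difference between 3′ and 5′ ends, a sign of shorter RNA, yet the pool, without that sign, was also high, with its lowest array 2.26 above the highest of the other 4 mice in the 4-gene mean. Younger neutrophils in some mice remain a candidate explanation, untested by any measure of cell age: the 4-gene mean was 12.46 in mouse 3, 6.80 to 7.45 in the other mice and 10.42 in the pool, between both, though saturation can lower the highest of these values.

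The third pattern is the higher level of platelet genes in the pool. A lower share of neutrophils in the pool would raise the markers of all other cells. It is argued against because the other 6 lists of such cells were higher in the pool by only 0.16 to 0.63 on the log2 scale, the highest of these in monocytes, against 1.84 for platelets. These values depend on mice 4 and 5. Without mouse 5, mice minus pool was 0.065 for B cells and -0.41 for monocytes, against -1.80 for platelets. Without mice 4 and 5 it was 0.96 for B cells and 0.51 for MHC class II, against -1.87 for platelets. The handling of the pooled blood, such as platelets that clump or bind to neutrophils during mixing, may have caused it, but with 1 pool this cannot be told apart from mice whose own samples held more platelets. No biological explanation was tested, since the mice of the pool were not measured singly.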

How the results depend on the processing

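The sets without mice 4 and 5 and the ordinary fit without mouse 5 were chosen after the results were seen, as was the count of other splits for the variance test, while the other alternatives, and the splits for the mean comparison and for the gene lists, were planned.

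The number of genes more variable between mice, 7165, kept its order of size under another quantile normalization (8381), median centring (7040), the probe set with the median mean (5450), without probe sets that can match several transcripts (6897), without the intensity trend (6499) and with robust moderation (7138). It was 10967 without a filter and 4432 above the 75th percentile, where more and fewer genes were tested, 3760 by a plain F test, 4752 after regression on the markers of other blood cells, and by the limma test on absolute deviations 0 (5754 at an unadjusted p under 0.05); the cause was not tested for these 3. Leaving out 1 array gave 2176 to 7594, with 2176 without mouse 5, and it was 76 without mice 4 and 5, where fewer arrays of a smaller spread were left. The opposite direction gave 0 throughout, with 1 gene at an unadjusted p under 0.05 in the limma test of all arrays. Of 100 splits of the 10 arrays, drawn from all possible ones, 1, the real one, gave as many genes. The median of the others was 1341 and the highest 6329, so other splits of these arrays also call many genes. The rank of the real split rests on mice 4 and 5 and was counted after the result was seen, so it does not exclude chance. The exact permutation p of the median variance ratio was 0.111 without mouse 5 and 0.625 without both. A batch of mice 4 and 5 would hold individual mice only, so batch and group cannot be told apart for them.

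The median log2 variance ratio, 2.88, was 1.23 to 3.21 with 1 array left out, with 1.23 (exact p = 0.111) without mouse 5, and -0.42 (exact p = 0.625) without mice 4 and 5, a reversal that comes from leaving out the most distant arrays. After regression on the markers of other blood cells it was 2.34 (permutation p = 0.0317). The median between-mouse SD was 0.22 to 0.58 with 1 array left out, 0 without mice 4 and 5 and 0.33 after that regression. The share of genes spanning over 2-fold between mice was 33.3% to 67.6%, 8.48% and 43.4% in the same sets. Each of these 3 measures was lowest without mouse 5 among the sets with 1 array left out.

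For the variance ratio of gene lists, where the smallest adjusted p of a single list is 0.198, 0 lists passed under the filters, scalings and probe set choices, 0 to 5 with 1 array left out, with 5 without pool 5, and 1, that of ribosomal proteins, by camera on absolute deviations (0 with an estimated correlation). The cause was not tested. The spread of marker levels passed for 2 lists, for 3 with quantile normalization (adding immature granules) and with median centring (adding platelets), and for 0 to 3 with 1 array left out. It was 0 without any 1 of the mice, where the p rose and the cause was not tested. The SD ratios without mouse 5 were 4.62 for B cells and 4.96 for MHC class II, against 4.54 and 5.16 with all arrays. With any 1 array left out, the log2 SD ratio of MHC class II was at least 2.16. The count was also 0 without mice 4 and 5, the arrays with the low levels, where the smallest possible p, 0.0179, keeps a single list from passing. The log2 SD ratio of the MHC class II level was then -0.93.

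The mean comparison (limma) called 0 genes under the filters, scalings and probe set choices, and with all arrays 38 were higher and 522 lower in mice at an unadjusted p under 0.05. It called 0 to 155 with 1 array left out, 155 without mouse 5 and 1 without mouse 3, and 468 without mice 4 and 5. In that last set the spread between the remaining mice was smaller, and mean differences moved too, from -0.32 to 0.96 for the B cell list. The cause of the larger count was not tested. The ordinary 2-group fit called 288, or 597 without mouse 5, array weights by group gave 220, and a replicate block gave 188 genes. These fits count technical replicates as mice. Every split gives at least the real 0, so the count of 100 of the 100 splits was fixed in advance and shows nothing about chance. For each other split the larger count was taken, with either group as the error, whereas the real split used the mice alone. The median of the other splits was 0 and the highest was 5541, so these counts are not like the real 0. A group of similar arrays used as the error can give a large count, and the cause was not tested.

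The replicate block joins mouse and pool arrays with the same number, which the data do not bear out: after centring, 3 of 5 such pairs correlated at over 0.1 across genes (-0.26 to 0.50), and 1 of 5 mice correlated best with the pool array of its own number. No paired analysis was possible because the pool came from other mice and the numbers do not pair the arrays. The block gave 3 gene lists in the mean comparison, platelets, ribosomal proteins and hypoxia and glycolysis, where the analysis without it gave 1.

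For the mean of gene lists, 1 list, that of platelets, passed under the 75th percentile, the scalings, the probe set choices, an estimated correlation and fry. Without a filter 7 passed, with oxidase and phagocytosis, ribosomal proteins, hypoxia and glycolysis, immediate early genes, neutrophil markers and oxidative phosphorylation added, all higher in the pool, and the larger number of genes compared is the change made. With 1 array left out, 1 to 5 passed. There were 5 without mouse 3, 4 without pool 5, 3 without mouse 1 and without mouse 4, and 2 without mouse 2. Without mice 4 and 5 it was 3, with B cell and MHC class II lists higher in the mice, where their low arrays were left out, but with an estimated correlation 0 passed (adjusted p of 0.967 and 0.998 for these lists), and by fry 2, platelets among them and neither of these lists. In 99 of 100 splits at least 1 list passed, the median of the others was 8 and the highest 16, so chance cannot be excluded by this count, and the larger counts point to a structure of the arrays.

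Among named genes, the log2 variance ratio kept its direction and its side of the threshold in 1557 of 1726 comparisons with an alternative, lost the threshold in 92, gained it in 4 and turned in 73. That of Hprt was -0.22 under quantile normalization (the cause was not tested). With 1 array left out it ranged, with the lowest value without mouse 3, for Ltf -0.019 to 5.58 and for Chil4 -0.15 to 5.38, and, with the lowest value without mouse 5, for Rab5if -0.80 to 6.56, Trim25 -0.89 to 7.83, Lbr -2.52 to 6.00, Clk1 -4.02 to 4.58, Ddx5 -2.11 to 4.66, Hnrnph2 -1.70 to 6.23, Cd3d -2.72 to 2.56, Oasl2 -4.33 to 4.60, Cmpk2 -2.54 to 3.23, Klf2 -0.21 to 6.11, Tnfaip2 -3.43 to 5.63, Sgk1 -1.27 to 5.62, Csnk1e -1.79 to 5.18, Gapdh -2.70 to 6.05, Atp5b -1.85 to 5.03, Rac2 -4.02 to 5.16, Ccr1 -2.80 to 4.10, Itgb2 -5.02 to 4.99, Pmaip1 -0.61 to 3.96, Bid -2.15 to 3.93, Actb -0.14 to 12.17, Gusb -1.35 to 3.80 and Sdha -0.45 to 6.07. Without mice 4 and 5 it was Rab5if -0.33, Trim25 -0.44, Lbr -2.99, H2az1 -6.36, Clk1 -3.86, Ddx5 -1.54, Crebbp -3.28, Hnrnph2 -1.26, Naca -0.094, Cd68 -0.38, H2-Ab1 -7.63, H2-Eb1 -2.38, H2-DMa -6.24, Cd3d -6.11, Prf1 -0.038, Ccl5 -1.39, Hbb-b2 -1.67, Bpgm -0.90, Oasl2 -4.12, Cmpk2 -2.04, Klf2 -2.65, Junb -1.95, Tnfaip2 -6.01, Sgk1 -1.77, Cebpd -3.36, Csnk1e -3.0, Gapdh -2.23, Mcm6 -0.0099, Rplp2 -3.0, Atp5c1 -0.68, Atp5b -4.99, Ndufv1 -1.44, Cyba -0.87, Rac2 -3.43, Ccr1 -4.55, Itgb2 -5.01, Mef2c -0.38, Pmaip1 -6.31, Bid -1.57, Apaf1 -2.43, Rpl13a -1.83, Actb -1.36, Eef2 -0.89, Gusb -2.30, Hprt -1.54, Sdha -3.06 and Cnn3 -0.23. In these sets the arrays that made the spread are left out.

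Mean differences of lists stayed on their side of the threshold in 402 of 422 comparisons and gained it in 20, variance shifts of lists in 417 of 422 and 5, marker SD ratios in 135 of 151 with 4 gained, 11 lost and 1 turned, and mean differences of named genes in 339 of 376 with 37 gained. Signal over background limits the weakest genes, as those with a mean under 4.58 were not tested. Among tested genes, the share called was 61.0% in the lowest quartile of signal and 76.2% in the highest with all arrays, and 24.3% and 10.6% without mouse 5.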

Other observations

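A few values fall outside the comparisons above, and the genes in this part were chosen after their values were seen. Some abundant neutrophil transcripts read at the top of the range of the arrays in all mice, where saturation can hide change. S100a8 read 12.85 to 13.29, S100a9 12.45 to 12.73 and Lyz2 12.31 to 12.89 in the mice, mouse 5 included, while Itgb2, at 12.08 to 12.22 in mice 1 to 4, read 7.80 in mouse 5.

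Some genes outside the granule lists were high in mouse 3 alone among the mice. Ctla4, an inhibitory receptor of T cells, read 7.62 in mouse 3, 4.19 to 4.83 in the other mice and 4.36 to 4.62 in the pool, unlike Camp, Ltf, Chil3 and Ngp, which were also high in the pool.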
